A study of Mus musculus with 15 samples.

How the data were processed

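The 15 samples were bone marrow cells of mice cultured for 14 days towards eosinophils. They fell into 8 groups by strain and assay as the labels give them: BALB/c RNA-seq, ATAC-seq and ChIP-seq for H3K27ac, H3K4me3 and H3K4me1 with 2 libraries each, BALB/c ChIP-seq for PU.1 with 1 library, and C57 ATAC-seq and H3K27ac ChIP-seq with 2 libraries each, where C57 is the name in the titles and BL6/57 the strain label. Per the labels' protocols, ATAC libraries followed the Omni-ATAC procedure, ChIP libraries were made by ChIPmentation, in which a transposase adds adapters during immunoprecipitation, and RNA libraries were made with a stranded kit for messenger RNA. A transposase cuts open DNA most readily, which can add signal at open chromatin to ChIP peaks.

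The authors deposited 1 table of read counts per gene for each RNA library and 1 peak list for each other library. The deposited counts are whole numbers without normalization. The submitters' processing notes name FastQC 0.11.7, Trim Galore 0.4.2, STAR 2.5, Picard 1.89, featureCounts, Bowtie2 2.3.4.1, bedtools 2.27.0, HOMER and the mm9 build, without the role of each. The peak caller and the strand setting of the counting are not given in the sources used here, so genes that overlap, or share reads with close copies, are uncertain. Peaks had been called per library, not on pooled libraries. Each deposited list gives a score, a fold enrichment and a −log10 q value per peak, which are the authors' own. The histone and ATAC lists have the layout of broad peaks and reach down to a −log10 q of 1, and the PU.1 list has the layout of narrow peaks and reaches down to 2, as tested on the files. These values were used to rank and filter peaks within a list. The scores of the 2 BALB/c ATAC lists were also averaged per region to give the ATAC score of the strata described below. No list held peaks that overlap each other. In the RNA tables, genes of the Y chromosome and globin genes were at 0 in both libraries, and it is not known whether they were counted.

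The counts were divided by the library total to give CPM. The depth of 40306679 and 30465490 counts sets the value of 3 counts at 0.0744 and 0.0985 CPM. Intervals and such floors cover counting error only. With a single group of RNA libraries there was no comparison between conditions. Instead 23 gene lists with 367 symbols, of which 365 matched the table directly or through older symbols (GRCm38.p6 gene table, used for names only), were set against all other genes: a gene counted as detected at 1 CPM or more in both libraries, and the share of detected members was tested with Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over the lists. The median log2(CPM + 1) of each list, with a pseudocount of 1, was placed among 10000 random lists of equal size. Genes are not replicates, so these tests describe the libraries. Scaling factors for the alternatives came from edgeR 4.0.16 (TMM) and DESeq2 1.42.0 (size factors) in R 4.3.3, and no count model was fitted. Genes named are the 20 with the highest mean CPM, per list up to 5 detected members with the highest mean CPM and up to 3 members not detected, all lineage transcription factors, and per strain and assay the 3 strain-only regions with the highest score in replicate 1. A gene that this rule takes is not reported here. Sex-linked genes were chosen after their values were seen. The 5 genes that escape X inactivation were chosen after Xist was seen and before their own values were; Kdm6a, another such gene, had already been seen and was left out.

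Peaks of different lists that shared at least 1 bp were joined into regions. A region was reproducible when both libraries of a group had a peak in it. Reproducible BALB/c ATAC regions were divided by overlap with reproducible regions into 4 classes: H3K4me3, H3K27ac without H3K4me3, H3K4me1 alone, and none of the 3 marks. The share with a PU.1 peak was compared between classes with Fisher's exact test, two-sided, and given with 95% Wilson intervals. Common odds ratios (Mantel-Haenszel) were taken over 25 strata, 5 of ATAC region width by 5 of ATAC score. Overlap of region sets was set against 100 random placements on the same chromosomes (bedtools 2.31.1), with chromosome lengths taken as the largest peak end in the lists, and peaks on the mitochondrial genome that start before its first base moved to that base. Strains were compared by the Jaccard index of the lists, with an exact permutation over the 3 splits of 4 libraries, and by the number of regions called in both libraries of a strain and neither of the other. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. On simulated data, all 300 and 200 planted strain-only regions among 20000 were found, a planted odds ratio of 3 gave 3.06, unrelated region sets gave a fold of 0.947, and in 25101 simulated genes 10 of 10 lists of raised genes and 0 of 10 random lists were called. Missed peaks were not simulated: each planted or shared region had a peak in every list it belonged to. The full recovery therefore says nothing on strain-only calls that arise from missed peaks. All 200 raised genes passed the CPM minimum, so each list of raised genes was detected in full. Their calls say nothing on lists detected only in part.

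Groups, tests, gene lists and most alternatives were fixed before the data were examined. Alternatives were CPM minimums of 5 and 0.5, TMM or size factor scaling, a background of genes with 10 or more counts, a pseudocount of 0.1, the higher-scoring 50% of peaks, equal list lengths, an overlap of 50% of the shorter region, marks in either library or within 1 kb, autosomes only, Jaccard in regions, replicate blocks, and each replicate left out. Tests planned between peaks and genes, namely expression by promoter marks and PU.1 near the gene lists, were not run because no annotation of mm9 was used here. The 8 files of the whole series that match no sample were not used.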

Results

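Eosinophils, granulocytes with granules of cationic proteins and a role in allergy and defence against helminths, were grown from mouse bone marrow for 14 days. The progenitors received stem cell factor and FLT3 ligand, each at 100 ng/mL, on days 0 to 3, and interleukin 5, the main growth factor of eosinophils, at 10 ng/mL on days 4 to 14. Messenger RNA was sequenced in 2 libraries of BALB/c cells. Open chromatin (ATAC-seq) and 3 histone modifications were mapped in 2 BALB/c libraries each: H3K4me3, found at active promoters, H3K27ac, found at active promoters and enhancers, and H3K4me1, found at enhancers. PU.1, a transcription factor of the ETS family that governs myeloid development, was mapped in 1 BALB/c library. ATAC and H3K27ac were also mapped in 2 libraries each from mice titled C57, whose strain label reads BL6/57. The design asks which genes these cells express, how open and modified chromatin and PU.1 are arranged along their genome, and how far open chromatin and acetylation differ between the strains.

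The RNA libraries held 40306679 and 30465490 counts over 25101 genes. The peak lists held 33919 and 33949 ATAC peaks in BALB/c, 36244 and 36768 ATAC peaks in C57, 20467 and 23203 H3K27ac peaks in BALB/c, and 14992 and 27527 H3K27ac peaks in C57. H3K4me3 gave 19085 and 19625 peaks, H3K4me1 gave 20139 and 17453 peaks, and PU.1 gave 62236 peaks. The sequencing depth behind the peak lists is unknown, so no interval for a single peak can be given. The labels do not say that libraries of a group came from separate cultures or animals, so the spread between peak libraries may be technical. In the 2 RNA libraries Xist, the RNA that silences an X chromosome, stood at 990 and 0.656 CPM. All 12 detected stromal and endothelial markers were higher in replicate 1. These values argue against a shared pool of cells behind both RNA libraries. The permutation tests over libraries measure only the spread between libraries, and Fisher's exact tests run over genes or regions and hold no such spread.

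The most abundant transcripts included eosinophil products. Prg2, which encodes major basic protein of the granule core, ranked 3 of all genes with 4053 ± 202 CPM (counts scaled by the library total; mean ± SD, n = 2, as for all levels that follow). Epx, which encodes eosinophil peroxidase, stood at 2766 ± 166 CPM, and Alox15, a lipoxygenase that makes lipid mediators, at 2583 ± 55.4 CPM. Csf2rb, the signalling chain of the interleukin 5 receptor, reached 3291 ± 612 CPM and the chemokine gene Ccl6 3041 ± 341 CPM. The secreted matrix protein gene Thbs1 reached 3451 ± 220 CPM. The other genes among the top 20 encoded actin and cytoskeletal proteins (Actb at 4386 ± 530, Myh9 at 4320 ± 280, Actg1 at 2947 ± 262, Flna at 2603 ± 133, Tln1 at 2272 ± 96.5 and Syne1 at 3055 ± 108 CPM), lysosomal proteins (Ctsd at 3509 ± 480, Psap at 3314 ± 424, Ctsb at 3011 ± 311 and Man2b1 at 2903 ± 238 CPM) and Pkm, Ftl1, Aldoa and Eef1a1, between 2321 and 2428 CPM. Together the top 20 genes of each library took 5.81% and 6.40% of its counts.

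Genes of the eosinophil programme were detected nearly throughout. At least 1 CPM in both libraries, the minimum used for detection, was reached by 11927 genes (47.5%). All 20 surface and receptor genes passed it, with Cd24a at 2119 ± 169 and Itgam, an integrin of myeloid cells, at 2035 ± 120 CPM. Csf2rb2, a close copy of Csf2rb, stood at 1753 ± 340 CPM. Of the 9 granule protein genes 8 were detected. Ear1 stood at 1683 ± 24.9, Prg3 at 645 ± 63.0 and Ear2 at 128 ± 6.49 CPM, while Ear3 had 0 counts in each library, where 3 counts would equal 0.0744 and 0.0985 CPM. The Ear ribonuclease genes and the Csf2rb pair are near-identical copies, so how their reads were shared is uncertain. Lipid mediator enzymes were detected in 11 of 12 cases, led after Alox15 by Alox5 at 820 ± 57.9 and Alox5ap at 681 ± 57.1 CPM, with Lta4h at 246 ± 7.16 and Tbxas1 at 200.03 ± 10.2 CPM. Ptgds had 0 and 1 count. Among 24 cytokines and chemokines 18 were detected, including Ccl9 at 505 ± 9.66, Tgfb1 at 386 ± 21.6 and Retnla at 163 ± 27.3 CPM, while Il10, Areg and Ccl11 stood at or below 0.239 CPM on average. Each of these lists held a larger share of detected genes than all other genes of the table (Fisher's exact test, two-sided, Benjamini-Hochberg over 23 lists: adjusted p = 2.62e-06 for surface and receptor genes, 0.0246 for granule proteins, 0.00534 for lipid enzymes and 0.0133 for cytokines). The granule call ended at a minimum of 0.5 CPM, with an adjusted p of 0.05005, and the cytokine call ended at a minimum of 5 CPM, with 58.3% detected. Against only the genes with 10 or more counts none of these calls held, and the cytokine share, 78.3%, lay below that of other genes. The surface, granule and lipid lists were at 100% there, the highest share possible, so for them not passing does not show a low share.

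All 18 transcription factors of the eosinophil lineage list were detected (adjusted p = 5.8e-06). Cebpe, a C/EBP factor needed for granule formation, was highest at 486 ± 35.2 CPM, followed by Spi1, which encodes PU.1, at 423 ± 17.6 CPM. Trib1 stood at 319 ± 9.65, Id2 at 306 ± 10.9 and Xbp1, a regulator of the secretory pathway, at 295 ± 4.77 CPM. Cebpb stood at 178 ± 23.3, Gfi1b at 162 ± 14.9, Gata1, the factor that sets eosinophil fate, at 153 ± 4.11, Ikzf2 at 152 ± 1.68, Stat5b at 149 ± 3.75 and Id1 at 142 ± 2.38 CPM. Lower levels were those of Runx1 (127 ± 16.6), Cebpa (104 ± 6.48), Gata2 (97.0 ± 24.2), Zfpm1 (49.3 ± 2.82), Stat5a (41.6 ± 0.124), Irf8 (35.6 ± 2.63) and Gfi1 (3.18 ± 0.414 CPM). By family, 14 of 19 ETS genes (adjusted p = 0.0484, Elf4 at 344 ± 8.11, Etv3 at 137 ± 1.19, Elf1 at 114 ± 2.29 and Etv6 at 102 ± 0.368 CPM), 7 of 7 C/EBP genes (adjusted p = 0.0105, Cebpg at 64.5 ± 5.21 and Cebpz at 49.9 ± 1.01 CPM) and 10 of 11 AP-1 genes (adjusted p = 0.00939, Fosl2 at 286 ± 8.22, Jund at 275 ± 20.8, Junb at 166 ± 7.46, Atf3 at 80.6 ± 4.52 and Jun at 56.2 ± 3.04 CPM) were detected. Of the GATA family only Gata1 and Gata2 passed, 2 of 6, and Gata3 stood at 0.123 ± 0.104 CPM (adjusted p = 0.721). The RUNX family, 4 of 5 detected, did not pass the test (adjusted p = 0.239), with Cbfb at 84.5 ± 4.06, Runx2 at 70.0 ± 0.308 and Runx3 at 42.9 ± 1.84 CPM.

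All 22 innate sensing receptors (adjusted p = 1.77e-06) and all 19 survival and apoptosis regulators (adjusted p = 4.13e-06) were detected. The complement receptor gene C3ar1 stood at 591 ± 56.0, the Fc receptor genes Fcgr2b and Fcgr3 at 495 ± 21.6 and 452 ± 40.8, Tlr4 at 213 ± 17.0 and Clec7a at 153 ± 0.542 CPM. Mcl1, which blocks apoptosis, stood at 733 ± 68.7 CPM and the kinase gene Pim1 at 550.0 ± 18.2 CPM. Bcl2a1b stood at 228 ± 3.27 and Bak1 at 134 ± 4.40 CPM. All 20 proliferation genes were detected as well (adjusted p = 2.62e-06), with Mki67 at 456 ± 50.6, Top2a at 227 ± 35.6, Pcna at 160 ± 11.3, Mcm6 at 99.1 ± 7.49 and Mcm3 at 82.9 ± 11.2 CPM. Housekeeping genes were detected in 14 of 14 cases (adjusted p = 9.79e-05), among them Gapdh at 1507 ± 70.9, Pgk1 at 1371 ± 51.8 and Rplp0 at 991 ± 71.0 CPM. Genes of unrelated tissues were detected in 1 of 20 cases, Syp at 1.59 ± 0.387 CPM, a smaller share than other genes (adjusted p = 0.00016).

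**Figure D1:**
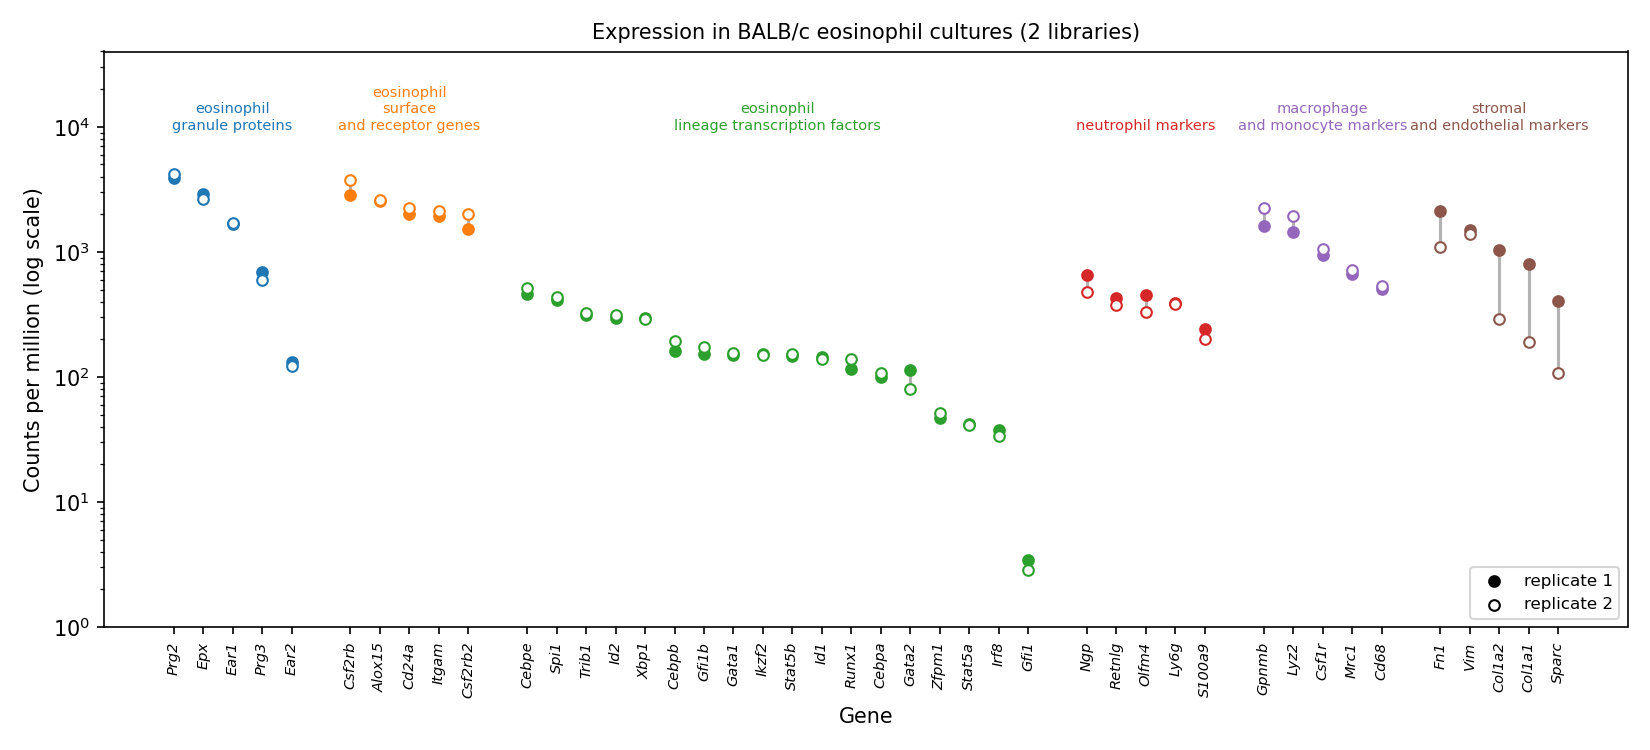
CPM, on a log axis, of the detected genes named from 6 lists in the 2 BALB/c RNA libraries (filled, replicate 1; open, replicate 2). Prg2 and Epx lie at 2649 CPM or more in each library, and the stromal genes Col1a1, Col1a2 and Sparc are the genes shown whose libraries lie farthest apart.

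Transcripts used as markers of other cell types were also present. All 18 neutrophil markers (adjusted p = 5.8e-06) and 18 of 20 macrophage and monocyte markers (adjusted p = 0.000345) were detected. The granule gene Ngp stood at 570 ± 125, Retnlg at 400 ± 37.4, Olfm4 at 392 ± 82.9, Ly6g at 385 ± 5.11 and S100a9 at 222 ± 27.3 CPM. Gpnmb stood at 1926 ± 447, Lyz2 at 1675 ± 348, Csf1r at 998 ± 77.5, Mrc1 at 690.1 ± 38.8 and Cd68 at 519 ± 19.8 CPM, with Marco at 0 counts. Dendritic cell markers were detected in 12 of 15 cases (adjusted p = 0.0246), but only in 46.7% at a minimum of 5 CPM, which ended the call. Their leading genes belong to antigen presentation, with H2-Aa at 110 and 193 CPM in replicates 1 and 2 and Cd74 at 224 and 365 CPM. Stromal and endothelial markers were detected in 12 of 15 cases (adjusted p = 0.0246), and these differed between the libraries. Col1a1, a collagen of fibroblasts, stood at 807 CPM in replicate 1 and 189 CPM in replicate 2, Col1a2 at 1040 and 291, Sparc at 404 and 108 and Fn1 at 2113 and 1090 CPM, while Vim was close at 1508 and 1380 CPM. The lists of mast cells and basophils (7 of 16 detected, adjusted p = 0.807), lymphoid cells (7 of 19, adjusted p = 0.406), erythroid cells and megakaryocytes (6 of 17, adjusted p = 0.394) and stem and progenitor cells (11 of 15, adjusted p = 0.0859) did not pass the test. The last passed it with 80.0% detected, at a minimum of 0.5 CPM and in replicate 1 alone. Their leading genes were Hdc at 126 ± 31.5, Il7r at 58.8 ± 15.2, Itga2b at 309 ± 2.38 and Gata2 at 97.0 ± 24.2 CPM, and the globin gene Hba-a1 was listed at 0.

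In total 17 of the 23 lists passed, 16 with a higher and 1 with a lower share than other genes. With only the 14674 genes of 10 or more counts as background, of which 81.3% were detected, 0 lists passed. Lists with all members detected also fell short there, such as innate sensing receptors at 100% (Fisher's exact test, two-sided, adjusted p = 0.125). This background therefore left lists of such size little or no room to pass with a higher share. The median of log2(CPM + 1) ranked within the lowest or the highest 2.5% of random lists of equal size for 16 lists, with the unrelated tissues at the low end and the others at the high end. The median of the unrelated tissues, 0, equals the lower limit of the random lists, and no random list can lie below it. Their percentile of 1.44 comes from tied lists counted in part, so this low call rests on how ties are counted. Across genes, which are not independent replicates, the log2(CPM + 1) values of the libraries had a Pearson r of 0.996. The libraries differed by more than sampling noise, with a chi-square of 22.3 per degree of freedom, and 284 detected genes (2.38%) lay more than 2-fold apart.

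In the BALB/c cells 27402 ATAC regions, 17611 H3K4me3 regions, 17787 H3K27ac regions and 11015 H3K4me1 regions were called in both libraries. These reproducible regions made up 68.8%, 86.2%, 71.8% and 42.0% of all merged regions of each assay. H3K4me3 marked 14821 of the open regions (54.1%). A further 3697 (13.5%) carried H3K27ac without H3K4me3, 1962 (7.16%) carried H3K4me1 alone, and 6922 (25.3%) carried none of the 3 marks. Only marks called in both libraries count here, so a region classed as without a mark may hold a peak of it in a single library. H3K27ac lay at 55.6% of the ATAC regions, where random placement on the same chromosomes gave 1.34%, which is 41.4-fold, and at 67.2% of the H3K4me3 regions (37.0-fold). H3K4me1 lay at 20.1% of the ATAC regions (24.2-fold), 24.95% of the H3K27ac regions (23.9-fold) and 13.5% of the H3K4me3 regions (12.2-fold), the lowest fold of the 10 pairs tested. Each pair exceeded all 100 placements, and 0.0099 is the smallest p that 100 placements can give.

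PU.1 peaks overlapped most open regions, and more often those with H3K27ac than those with H3K4me3 and no H3K27ac. Of the 27402 ATAC regions, 21298 (77.7%) overlapped a PU.1 peak, against 2.85% for random placements (27.3-fold). Among regions with H3K27ac but no H3K4me3, 91.6% overlapped a PU.1 peak (95% Wilson interval 90.7 to 92.5%), compared with 83.6% of H3K4me3 regions (83.0 to 84.2%), 83.2% of regions with H3K4me1 alone (81.5 to 84.8%) and 56.2% of regions with none of the 3 marks (55.0 to 57.3%). The acetylated class exceeded the H3K4me3 class by 8.05 percentage points (odds ratio 2.15, Fisher's exact test, two-sided, p = 8.51e-39, adjusted p = 1.28e-38 over 6 comparisons) and the class with H3K4me1 alone by 8.41 points (odds ratio 2.21, p = 1.73e-20, adjusted p = 2.07e-20). With the higher-scoring 50% of PU.1 peaks these differences were 17.3 and 14.9 points, and with marks called in either library the latter was 14.3 points. It exceeded the unmarked class by 35.5 points, with an odds ratio of 8.56. The H3K4me3 class and the class with H3K4me1 alone differed by 0.359 points, which did not pass the test (adjusted p = 0.697). In 6 alternatives the difference passed Fisher's exact test before adjustment: it was -2.47 points with the higher-scoring 50% of PU.1 peaks (p = 0.0375), 7.39 with marks called in either library (p = 5.26e-18), 1.93 without ATAC replicate 2 (p = 0.0238), 3.05 without H3K27ac replicate 1 (p = 0.00268), and 2.17 and 2.71 without H3K4me1 replicate 1 or 2 (p = 0.00856 and 0.000881). Among ATAC regions of like width and score, the acetylated class had higher odds of a PU.1 peak than the H3K4me3 class (common odds ratio 5.25, 95% interval 4.58 to 6.01), and H3K4me3 regions had lower odds of a PU.1 peak than regions with H3K4me1 alone (common odds ratio 0.323, 95% interval 0.280 to 0.372). Within the H3K4me3 class, PU.1 lay at 91.8% of the 11531 regions that also carried H3K27ac (91.3 to 92.3%) and at 54.9% of the 3290 regions without it (53.2 to 56.6%), an odds ratio of 9.15, which was 4.60 (4.14 to 5.11) among regions of like width and score. The regions with H3K4me3 and no other mark, at 53.8% (52.0 to 55.7%), lay slightly below those with none of the marks, at 56.2% (55.0 to 57.3%). These intervals overlapped in part, which does not show equal shares, and the difference was not tested. PU.1 was mapped in 1 library, so its peaks have no replicate check, and the intervals cover counting error over regions only.

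**Figure D2:**
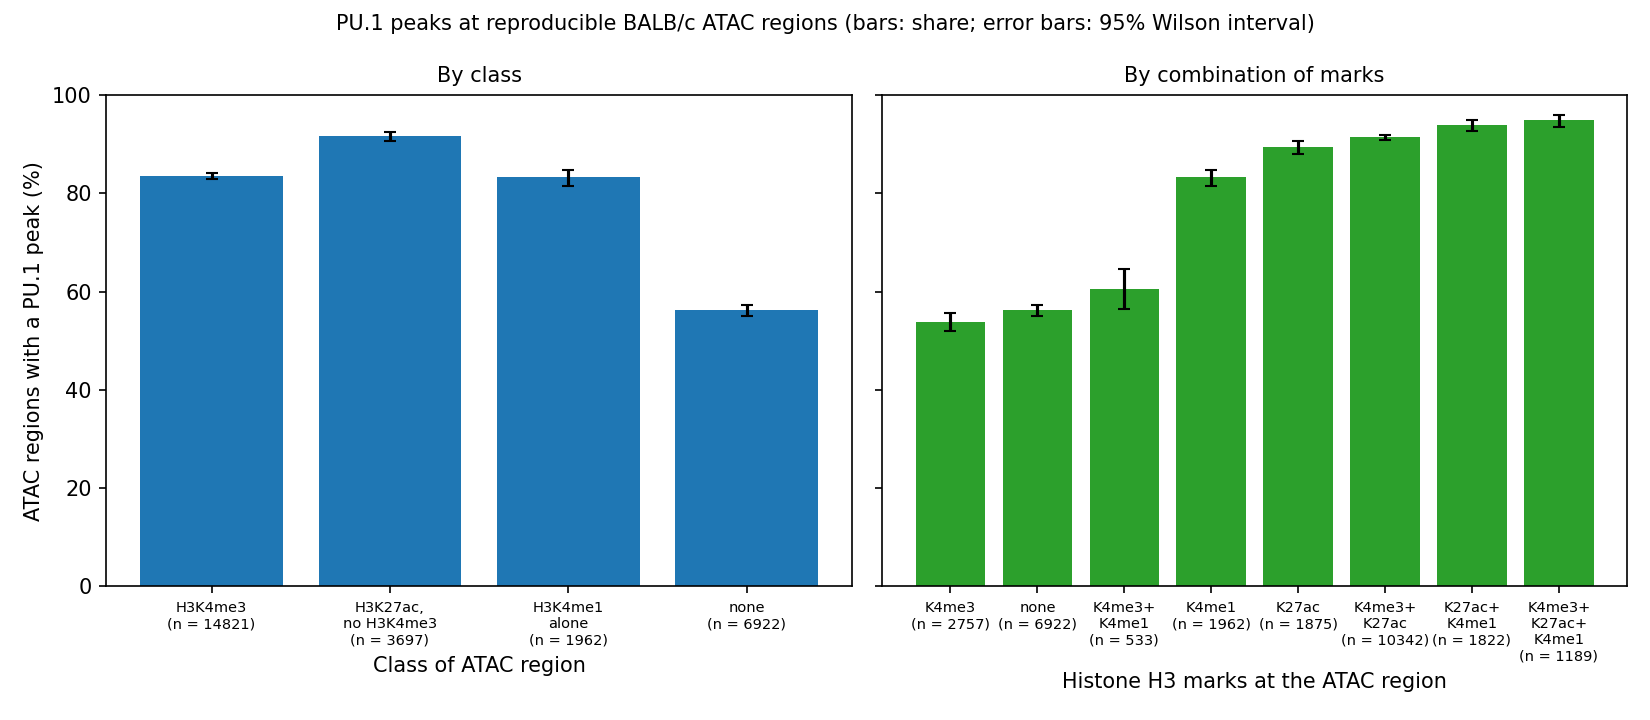
Share of reproducible BALB/c ATAC regions that overlap a PU.1 peak, in percent from 0 to 100, by class (left) and by combination of the 3 histone marks (right), with 95% Wilson intervals and the number of regions. Every combination with H3K27ac lies at 89.4% or more, and regions with H3K4me3 alone lie at 53.8%.

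Open chromatin of the BALB/c and C57 cells overlapped largely, with more overlap within than between strains. The Jaccard index in base pairs, the shared length over the joint length, was 0.617 for the BALB/c pair and 0.606 for the C57 pair of ATAC lists, and between 0.554 and 0.579 for the 4 pairs across strains. The mean within minus between was 0.0444, the highest of the 3 ways to split the libraries, and the other splits gave -0.0209 and -0.0234. The exact permutation test gave p = 0.333, one-sided, the smallest value that 2 libraries against 2 allow, so the design cannot reach 0.05. Of 49646 merged ATAC regions, 23392 (47.1%) were called in all 4 libraries, 1556 (3.13%) in both BALB/c libraries and neither C57 library, and 2564 (5.16%) in both C57 libraries and neither BALB/c library. The other splits gave 741 and 900, and 918 and 735, regions. With lists limited to the same number of top peaks the strain-only counts were 1988 for BALB/c and 1941 for C57, though equal lengths by design bring these counts together. Leaving out any 1 of the 4 libraries, which loosens the definition, raised the counts to between 2576 and 4656 for BALB/c and between 4248 and 6492 for C57.

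**Figure D3:**
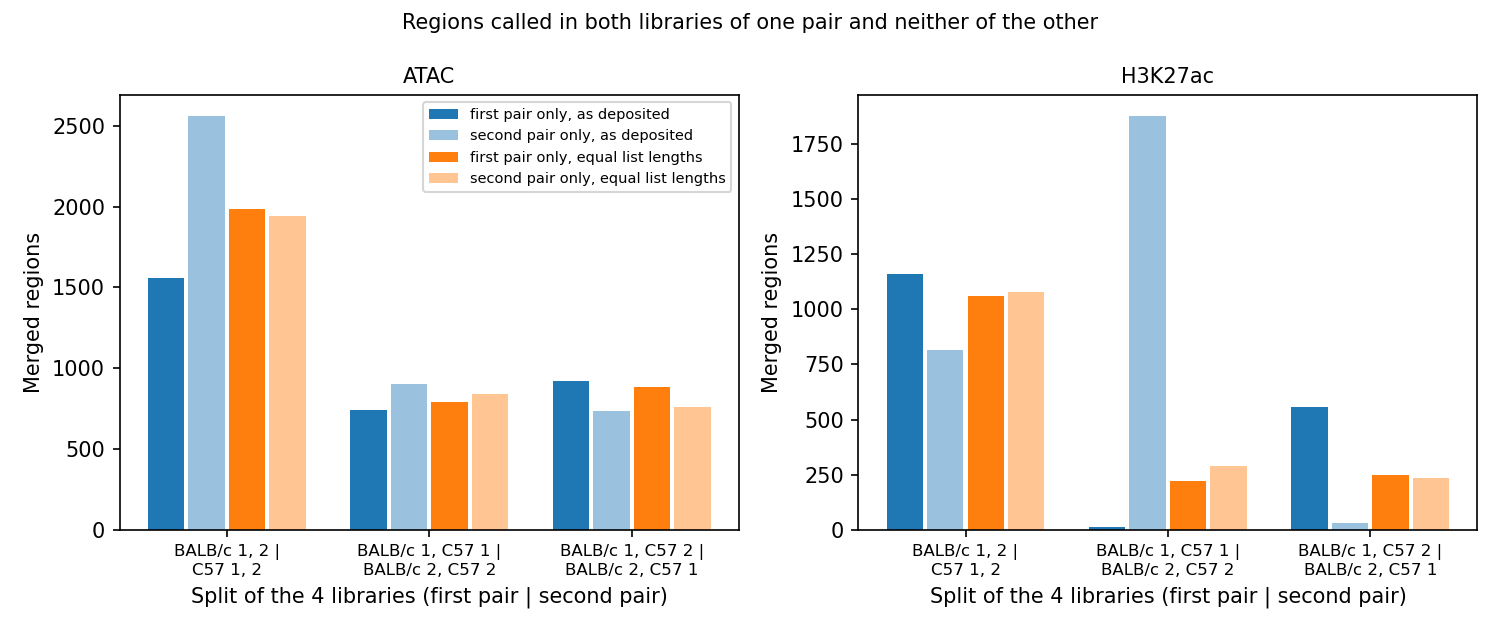
Number of merged regions called in both libraries of the first pair and neither of the second (dark bars), and the reverse (pale bars), for each split of the 4 libraries, with lists as deposited (blue) and limited to equal lengths (orange). For ATAC the strain split gives 1556 and 2564 regions as deposited, above the other splits, while for H3K27ac as deposited the split of replicates 1 from replicates 2 gives 10 and 1879 regions.

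The ATAC and H3K27ac lists of the strains also differed on the Y chromosome, though Y calls did not divide by strain over all lists. Every list shared 1 Y region, at 2651958 to 2652566 of the mm9 build. Apart from that region the C57 ATAC lists held 5 Y regions each and the C57 H3K27ac lists 3 and 5, while the BALB/c ATAC, H3K27ac, H3K4me3 and H3K4me1 lists held 0 and the BALB/c PU.1 list held 12. The regions at 346134 to 347548 and at 622071 to 623305 of chromosome Y were called in the 4 C57 libraries and the BALB/c PU.1 library, and in no other list.

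Acetylation lists as deposited did not separate by strain in the same way. The Jaccard index was 0.650 for the BALB/c pair of H3K27ac lists but 0.453 for the C57 pair, below all 4 pairs across strains, which lay between 0.461 and 0.560. The mean within minus between was 0.0433 (exact permutation p = 0.333, one-sided, the smallest possible), against 0.00803 and -0.0513 for the other splits. Without BALB/c replicate 1 or 2, where the C57 pair alone gives the within-strain value, the difference was -0.0582 and -0.0525. Without C57 replicate 1 it was 0.112 and without C57 replicate 2 it was 0.172. Of 31700 merged regions 12733 (40.2%) were called in all 4 libraries, 1162 only in both BALB/c libraries and 816 only in both C57 libraries. The split of replicates 1 from replicates 2 gave 1879 regions found only in the replicates 2, which had the longer lists. With equal list lengths the strain-only counts were 1059 and 1078, a total of 2137, and the other splits gave totals of 511 and 486 regions. Without BALB/c replicate 1, BALB/c replicate 2 or C57 replicate 2 the BALB/c-only count rose to 3499, 2106 and 4880. Without BALB/c replicate 2 or C57 replicate 1 the C57-only count rose to 1445 and 7703.

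**Figure D4:**
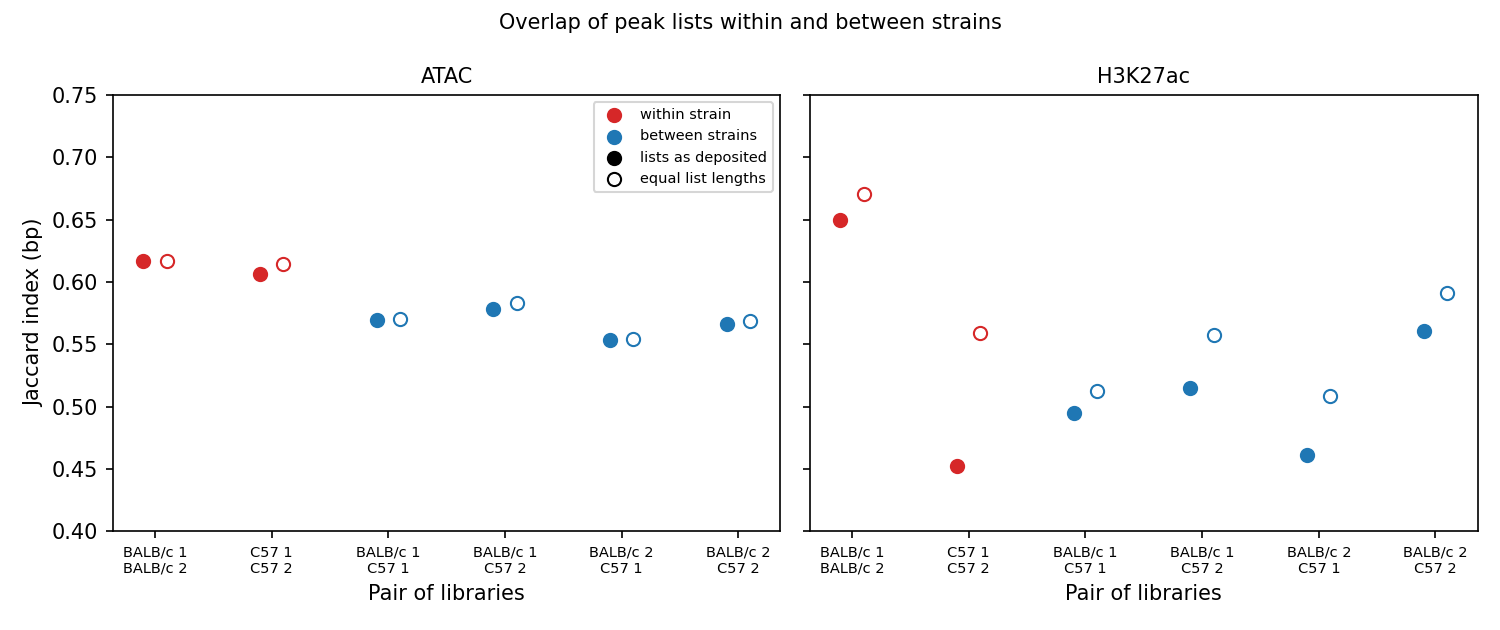
Jaccard index in base pairs (axis from 0.4) for each pair of ATAC lists (left) and H3K27ac lists (right), within strains in red and between strains in blue, with lists as deposited (filled) and limited to equal lengths (open). Both within-strain ATAC pairs lie above all pairs between strains, and the C57 pair of H3K27ac lists, at 0.453 as deposited, lies below them.

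Where both accessibility and acetylation calls differed between the strains, they mostly did so in the same direction. Of the 1556 BALB/c-only ATAC regions, 128 (8.23%) overlapped a BALB/c-only H3K27ac region and 11 (0.707%) a C57-only one. Of the 2564 C57-only ATAC regions, 154 (6.01%) overlapped a C57-only H3K27ac region and 14 (0.546%) a BALB/c-only one. The odds ratio was 128 (Fisher's exact test, two-sided, p = 1.18e-55), and it lay between 34.6 and 58.1 when any 1 of the 8 libraries was left out. The transposase used in ChIPmentation can add signal at open chromatin, and poorer mapping of BALB/c reads could remove both calls at a site. Neither was tested here, so the correspondence does not show that accessibility and acetylation each changed on their own. Overlaps in the opposite direction rose most without C57 H3K27ac replicate 1, when BALB/c-only ATAC regions overlapped 129 BALB/c-only and 96 C57-only H3K27ac regions, and without C57 H3K27ac replicate 2, when C57-only ATAC regions overlapped 152 C57-only and 113 BALB/c-only ones. ATAC regions called in all 4 libraries overlapped such regions in 1.17% and 1.27% of cases. PU.1, mapped in BALB/c cells, was called at 82.4% of the ATAC regions found in all 4 libraries (81.9 to 82.9%), at 48.8% of BALB/c-only regions (46.4 to 51.3%) and at 44.0% of C57-only regions (42.1 to 45.9%), whose median widths were 717, 358 and 295 bp. The strain-only groups differed by 4.85 points (Fisher's exact test, two-sided, p = 0.0027, unchanged by adjustment over 3 comparisons), but without BALB/c ATAC replicate 1 or 2 the difference was -8.79 and -6.57 points, without C57 ATAC replicate 1 or 2 it was 13.3 and 10.1 points, and with the higher-scoring 50% of PU.1 peaks it was 2.80 points and no longer passed the test (p = 0.0539). With equal list lengths it was 10.6 points (Fisher's exact test, p = 2.26e-11).

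The strain-only regions with the highest score in replicate 1 showed this correspondence in part. The top BALB/c-only ATAC region lay on chromosome 17 from 4626121 to 4626626, with scores of 462 and 48 in the BALB/c libraries, and coincided with the top BALB/c-only H3K27ac region at 4626024 to 4626757 (scores 159 and 147). The next ATAC regions lay on chromosome 14 from 46432431 to 46432660 (240 and 216) and chromosome 17 from 56339356 to 56339592 (225 and 42). The latter had an H3K27ac peak in both BALB/c libraries and neither C57 library, and the region on chromosome 14 in BALB/c replicate 1 alone. The C57-only ATAC regions lay on chromosome 18 from 7608867 to 7609788 (216 and 210), chromosome 11 from 71064826 to 71065282 (169 and 184) and chromosome 8 from 37286185 to 37286498 (147 and 142), and those on chromosomes 18 and 11 had an H3K27ac peak in both C57 libraries and in neither BALB/c library. None of these ATAC regions overlapped a PU.1 peak. The other BALB/c-only H3K27ac regions lay on chromosome 17 from 24479579 to 24480123 (125 and 138) and chromosome 3 from 21597156 to 21597669 (116 and 65), each with a PU.1 peak. The former had an ATAC peak in both BALB/c libraries and neither C57 library, and the latter in all 4 libraries. The C57-only H3K27ac regions lay on chromosome 11 from 116255529 to 116256750 (125 and 73), chromosome 5 from 37051954 to 37052425 (116 and 218, with a PU.1 peak) and chromosome 4 from 140765882 to 140767356 (94 and 81). All had an ATAC peak in both C57 libraries, and those on chromosomes 11 and 5 also had one in BALB/c replicate 2. Scores are the authors' own and rank peaks within a list only, and coordinates are those of mm9, for which no gene annotation was used here.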

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

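Of 370 values recomputed under alternatives, 311 counted as the same, by direction and side of the threshold, or for counts by staying within 1.5 times. A list share that passed in neither setting also counted as the same where its direction turned. Against genes with 10 or more counts, the GATA family (100%) thus turned higher than other genes. RUNX (80.0%) and stem and progenitor markers (78.6%) turned lower there. Alternatives chosen after seeing the data were leaving out libraries for the Jaccard values, equal lengths combined with Jaccard in regions, H3K27ac lists alone of equal length at strain-only ATAC regions (odds ratio 71.4), and autosomes alone for PU.1 at strain-only regions. The Jaccard difference of ATAC stayed between 0.0319 and 0.0549 in 10 alternatives, and the H3K27ac odds ratio stayed between 34.6 and 170.3. The 30 overlap folds stayed above 1 but moved in size, between 7.57 and 64.2. For H3K4me3 regions with H3K4me1 they ranged from 7.57 to 14.0, and for H3K4me3 regions with H3K27ac from 32.4 to 60.9. With a background of genes with 10 or more counts 0 of 23 lists passed, where 81.3% of that background was detected. Lists detected in full did not pass there either, so for them that outcome does not show a low share. The shares detected there were 100% for granule, surface, lineage factor, lipid, innate, survival, C/EBP, neutrophil, proliferation and housekeeping lists, 94.7% for macrophages, 90.9% for AP-1, 87.5% for ETS, 85.7% for dendritic cells and for stromal cells, 50.0% for unrelated tissues and 78.3% for cytokines, which turned lower than other genes. At a minimum of 5 CPM cytokines (58.3%) and dendritic cells (46.7%) no longer passed. At 0.5 CPM granule proteins (88.9%) no longer passed and stem and progenitor markers (80.0%) did; the latter ranged from 73.3% to 80.0% without either replicate. The cause was not tested.

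With the higher-scoring 50% of peaks the strain-only counts were 802 and 1255 for ATAC and 595 and 521 for H3K27ac (BALB/c and C57), as shorter lists must give fewer. Without each replicate the ATAC counts ranged from 2576 to 4656 and from 4248 to 6492, and the H3K27ac counts from 1192 to 4880 and from 965 to 7703, because fewer lists must fit. The H3K27ac Jaccard difference ranged from -0.0582 to 0.172. The labels do not say that replicate numbers pair libraries across strains. Differences between replicates had a correlation across regions of -0.00162 (ATAC) and 0.000395 (H3K27ac) between the strains. With the replicate block the Jaccard differences were 0.0435 and 0.0235. Pairs 1 and 2 alone gave 6647 and 6446 BALB/c-only and 8761 and 9211 C57-only ATAC regions, and 6918 and 3567 BALB/c-only and 2004 and 8469 C57-only H3K27ac regions, since only 2 lists enter.

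PU.1 at H3K4me3 minus H3K4me1-alone regions was -2.47 points with the higher-scoring 50% of PU.1 peaks, 7.39 with marks in either library, and 0.542 to 3.05 without each replicate. PU.1 at BALB/c-only minus C57-only ATAC regions was 2.80 with the higher-scoring 50% and ranged from -8.79 to 13.3 without each replicate. Without an ATAC library of a strain, a call in its other library is enough to make a region strain-only, so the regions compared change. How far this accounts for the shift was not tested, nor was the cause of the shifts between H3K4me3 and H3K4me1-alone regions. Expression by promoter marks and PU.1 near the gene lists were not run. Unknown depth limits every statement on the absence of a peak.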

Other observations

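The tests of the sex of the cultures, of stromal cells and of width and score for H3K4me3 regions, with or without H3K27ac, were chosen only after the result was seen. ATAC regions found in a single strain carried BALB/c H3K4me3 and H3K27ac less often than regions found in all 4 libraries. H3K4me3 lay at 58.7% of the shared regions (95% Wilson interval 58.0 to 59.3%), at 26.99% of BALB/c-only regions (24.8 to 29.3%) and at 7.49% of C57-only regions (6.53 to 8.57%). H3K27ac lay at 61.3%, 22.9% and 9.40%. H3K4me1 varied less, with 20.7% of shared (20.2 to 21.2%), 18.9% of BALB/c-only (17.0 to 20.9%) and 12.6% of C57-only regions (11.3 to 13.9%). The intervals of shared and BALB/c-only regions overlapped for this mark, and the difference was not tested. The strain-only regions were also narrower (median 358 bp for BALB/c-only and 295 bp for C57-only, against 717 bp for shared regions), and width was not held equal in these shares. PU.1 was called in BALB/c cells at 44.0% of the ATAC regions called only in C57 libraries. The lack of a BALB/c ATAC call need not mean closed chromatin there, since depth is unknown.

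Most PU.1 peaks lay outside reproducible open chromatin. Of the 62236 peaks 37.4% overlapped a reproducible ATAC region, and the share was 22.5% in the lowest of 4 equal parts by score and 61.5% in the highest. Of the 38929 peaks outside, 85.9% had no ATAC peak in either BALB/c library, 8.92% carried H3K4me1, 7.71% H3K27ac and 6.11% H3K4me3. On chromosome X lay 0.554% of reproducible H3K4me1 regions (0.431 to 0.711%), against 2.16% of ATAC, 2.271% of H3K27ac and 3.00% of H3K4me3 regions.

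The higher PU.1 share at acetylated regions was weighed against region size and strength, since acetylated regions were wider (median 550 bp, against 341 bp for unmarked regions). Within 25 strata of ATAC width and score the common odds ratio of acetylated regions without H3K4me3 against unmarked regions was 5.23 (95% interval 4.58 to 5.97), compared with 8.56 without strata, which argues against size and score as the whole cause. For H3K4me3 regions against unmarked regions the common odds ratio was 1.07 (0.980 to 1.16), compared with 3.98 without strata, so width and score may account for the difference between these classes taken whole. For H3K4me3 regions against regions with H3K4me1 alone it was 0.323 (0.280 to 0.372), compared with 1.03 without strata. Both values pool H3K4me3 regions with and without H3K27ac. Between these the common odds ratio was 4.60 (4.14 to 5.11), so both are averages over unlike regions. The higher-scoring 50% of PU.1 peaks lay at 59.3% of H3K4me3 regions (58.5 to 60.0%) and 36.2% of unmarked regions (35.1 to 37.4%), which met the bound set beforehand against ChIP background at open promoters, but that bound was wrong, because width and score were not held equal, and background stays open. An effect of PU.1 on acetylation, or the reverse, was not tested.

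For the strain difference in ATAC calls, list length was argued against: with equal list lengths the lowest within-strain Jaccard index exceeded the highest between strains by 0.0307. Equal lengths do not equalize sequencing depth, which is unknown and stays open for ATAC too. A difference in sex, raised by the Y regions in C57 lists, stays open: 96.4% of strain-only regions lay on autosomes (95.8 to 97.0%), as do most of all ATAC regions, and chromosome X held 3.86% of BALB/c-only regions (3.01 to 4.93%), against 1.87% of C57-only regions (1.41 to 2.47%) and 2.09% of those in all 4 libraries (1.91 to 2.28%), while the Jaccard difference on autosomes alone, 0.0440, argues only against the sex chromosomes as the whole cause. Sequence differences that lie in blocks would cluster strain-only regions, and no clustering was seen at the scale of 1 Mb. The variance of strain-only counts over bins was 0.981 times its permuted mean and that of another split was 1.01. The counts were thinned to 1602 regions per split, a change from the test as first written, and without thinning the values were 0.963 and 1.01. This met the bound set beforehand against blocks, but the test was not tried on planted blocks. Splits that mix the strains gave 1641 and 1653 regions, so call noise may dilute clustering, and blocks stay open. Poorer mapping of BALB/c reads to the reference cannot be told apart from strain biology: the ratio of C57-only to BALB/c-only regions with equal list lengths, 0.976, met the bound of 1.5 set beforehand against this cause, but that bound was wrong, because equal lengths by design pull the ratio towards 1, while the lists as deposited gave 1.65 for ATAC and 0.702 for H3K27ac. For H3K27ac, equal lengths raised the mean difference in base pairs from 0.0433 to 0.0724, and counted in regions, a measure added later, both within-strain values (0.720 and 0.714) exceeded the highest between strains (0.651), but in base pairs the lowest within-strain value lay at -0.0316 relative to the highest between strains, so the measures differ and depth, which is unknown, stays open, as does strain biology, untested for both assays.

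The 2 RNA libraries differed in sex-linked and stromal genes. Xist, the RNA that silences an X chromosome in females, stood at 990 CPM in replicate 1 and 0.656 CPM in replicate 2, while the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty had 0 counts in each. A second X chromosome in cells of the first library only may explain this: 5 genes that escape X inactivation were all higher in replicate 1, with a median log2 ratio of 0.48, above 99.98% of matched random lists, and ranged from 0.07 for Utp14a to 0.78 for Eif2s3x. Stem and progenitor markers also lay above 99.98% of their matched lists, and further lists outside 95% are given below. The rank of the 5 genes thus does not by itself single out the X chromosome. All 12 detected members of the stromal and endothelial list were also higher in replicate 1 (median log2 ratio 1.21, where 95% of matched random lists lay between -0.08 and 0.08), but the list holds the collagen genes that drew attention to it, so whether the first library held more stromal cells stays open. Its most abundant members were Fn1 (2113 and 1090 CPM), Vim (1508 and 1380 CPM) and Col1a2 (1040 and 291 CPM), of which macrophages also express Fn1 and Vim.

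Other lists whose median log2 ratio of replicate 1 over replicate 2 lay outside 95% of matched random lists were mast cell and basophil markers (0.69, 6 of 7 higher in replicate 1), stem and progenitor markers (0.51, 9 of 11), proliferation genes (0.26, 20 of 20) and neutrophil markers (0.15, 13 of 18) on the higher side. On the lower side were dendritic cell markers (-0.45, 1 of 12 higher), lymphoid markers (-0.16, 2 of 7), erythroid and megakaryocyte markers (-0.16, 1 of 6), the C/EBP family (-0.13, 2 of 7) and the eosinophil lineage transcription factors (-0.06, 7 of 18).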
